A study of Homo sapiens with 18 samples.

How the data were processed

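Polyadenylated RNA was sequenced from the human melanoma cell lines SKmel147, which carries an NRAS mutation, and 501mel, which carries a BRAF mutation. ARID2, the gene targeted by CRISPR, encodes the DNA-binding subunit that marks the PBAF form of the SWI/SNF chromatin remodelling complex. Per the labels, SKmel147 was sequenced as 5 lines: Par without a construct, NT with a Cas9 and a guide construct, and the ARID2 KO lines KO1.4, KO1.5 and KO3.20 with the same kinds of construct. 501mel was sequenced as 4 lines: Par without a construct, NTC with a single vector for Cas9 and guide, and the ARID2 KO lines KO1.8 and KO5.2 with that vector. The labels do not spell out NT and NTC, and they are called transduced controls here. Each line had 2 libraries, made with a directional kit per the labels' protocols, so the series holds 18 libraries. Nothing in the labels says whether the 2 libraries of a line came from separate cultures, or whether a line was a clone or a pool. All p-values between libraries therefore measure the spread between these libraries, which may be technical.

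The deposited values are raw read counts per gene symbol, 1 column per library. Per the submitters' processing notes, the authors used STAR 2.6.0 and featureCounts, and the builds GRCh37 and hg19 are named. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies, such as the HLA, SSX, MAGEA and APOBEC3 families, and overlapping or antisense genes are uncertain for that reason. Each table lists 56629 symbols. For chromosome, GC content and transcript length, symbols were matched to GENCODE 29, whose assembly differs from the builds named by the submitters, and 35508 symbols matched, 1434 of them through an older symbol. That annotation served only to place genes on chromosomes, to order neighbours and to give GC content and length, and no coordinate from it is printed.

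Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each cell line was fitted separately with TMM scaling, the filterByExpr filter by line and 1 coefficient per line, and contrasts were tested with the quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg (BH) method, and a gene was called at an adjusted p under 0.05. The comparison of KO with controls was the mean of the KO lines minus the mean of Par and the transduced control, so each line had equal weight. Each KO line was also compared with the mean of the controls, and a gene counted as changed in every KO line if it was called with 1 sign in all of them. The transduced control minus Par served as background. The difference of the KO effect between the cell lines was the interaction contrast of a joint fit of all 18 libraries. Fold changes are log2 values with their standard errors (SE), and levels are CPM, counts divided by library size and scaled with TMM factors.

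All these tests take libraries of 1 line as replicates and leave out the differences between independent lines that have nothing to do with ARID2. For that reason each main count stands beside the count with the line as the replicate, from counts summed per line, and beside a limma 3.58.1 voom fit with the line as a random block. Within each cell line, the KO counts also stand beside simulations without any KO effect. In these, every line drifted as far as the control lines differed from each other. The same simulations were run after the GC and length correction. No such simulation was run for the difference between the cell lines.

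There were 29 gene lists, fixed before the data were examined, and they were tested with camera at a preset correlation of 0.01, BH-adjusted over the lists of a cell line. Members were also counted with p-values adjusted over the list alone. The genes named were set by a rule, also fixed before the data were examined. Per cell line it takes the 10 rising and the 10 falling genes called in the comparison and in every KO line, with a mean log2 CPM of at least 3 and a fold change larger than that between the control lines, ranked by the smallest change over the KO lines. Across cell lines it takes the 5 genes per direction that meet this in both, and the 5 per direction with the smallest p for the difference. It further takes up to 4 members per list, by smallest p, and always ARID2. XIST, Y-linked genes, clone-based names, pseudogenes, antisense and small RNA genes were left out of the ranking. Where other genes are named, the text says so.

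Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no low-count filter, a block for the replicate number, either control alone, each library or KO line left out, the line as replicate, the voom fit, a 2-fold limit and, for the lists, an estimated correlation. A correction of each library for trends on GC content and transcript length was added after the data had been seen. No column was left out of the tables, and no other file was analysed here.

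The steps were tested on simulated counts with 200 changed genes. For SKmel147, 65.6% of the genes changed by 1 log2 unit were recovered among 17718 genes, and 11.3% of all calls were unchanged genes. The corresponding values for 501mel were 93.8% and 5.95% among 15695 genes. At 0.5 log2 units, near the median size of 0.54 of the SKmel147 calls, 50% were recovered in SKmel147, and 1.56% in every KO line, against 71.6% and 61.2% in 501mel. Those simulations held no drift between lines. Library totals ranged from 21266522 to 35670140 counts in SKmel147 and from 16749707 to 20606855 in 501mel. The biological coefficient of variation, the spread between libraries of a line beyond counting error, was 0.134 in SKmel147 and 0.0478 in 501mel. A limit stated for a count of 0 covers counting error only.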

Results

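Gene expression was measured by sequencing of polyadenylated RNA in ARID2 KO lines and control lines of the melanoma cell lines SKmel147 and 501mel. SKmel147 had 10 libraries from 5 lines and 501mel had 8 libraries from 4 lines, with 2 libraries per line. The control lines of each cell line were the line without a construct (Par) and a transduced control (NT in SKmel147, NTC in 501mel). Totals ranged from 21266522 to 35670140 counts per library in SKmel147 and from 16749707 to 20606855 in 501mel. Libraries of 1 line differed by more than counting error, with a chi-square per degree of freedom of 15.1 to 39.2 in SKmel147 and 2.51 to 4.86 in 501mel. The comparisons asked which genes differed between ARID2 KO lines and controls, and whether the difference was alike in both cell lines. In SKmel147 the KO mean rests on 6 libraries of 3 lines, in 501mel on 4 libraries of 2 lines, and the control mean on 4 libraries of 2 lines in each.

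The RNA of the targeted gene ARID2 was lower in the KO libraries of both cell lines. In SKmel147 it was at 62.3 to 72.8 CPM in the control libraries and at 39.8 to 57.0 CPM in the KO libraries, a log2 fold change of −0.43 ± 0.08 (SE). KO1.5 and KO3.20 passed the test at −0.41 and −0.64, while KO1.4, at −0.25, did not (edgeR quasi-likelihood test, BH, adjusted p = 0.228). In 501mel it was at 40.9 to 43.2 CPM in the control libraries, at 30.9 and 32.0 CPM in KO1.8 and at 19.8 and 20.96 CPM in KO5.2, a log2 fold change of −0.73 ± 0.05. The transduced controls differed from Par by −0.12 in SKmel147 and 0.00 in 501mel. The adjusted p of KO against controls was 0.00390 in SKmel147 and 3.74e-08 in 501mel (edgeR quasi-likelihood test, BH). With the line as the replicate, ARID2 did not pass in either cell line, with adjusted p of 0.302 and 0.310 (edgeR, BH). A guide can disrupt a protein without lowering its RNA, so these levels do not measure the loss of the protein.

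**Figure D1:**
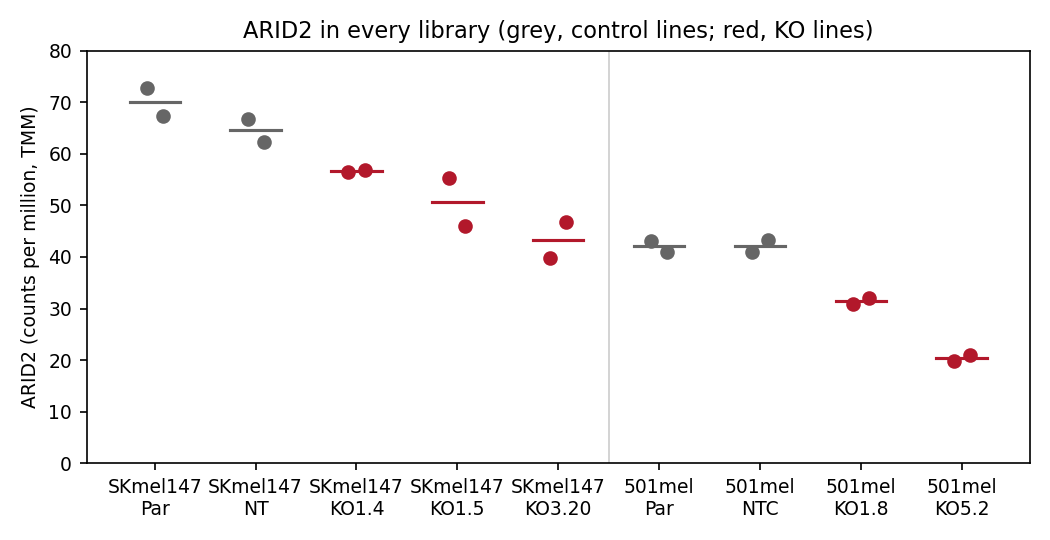
ARID2 in CPM, library-size-scaled counts (y axis) in each of the 18 libraries, by line (x axis); points are libraries and short horizontal lines are line means. All KO libraries lay below all control libraries of their cell line, from 39.8 to 57.0 CPM against 62.3 to 72.8 CPM in SKmel147.

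In SKmel147, the rising gene ranked first by its smallest change over the KO lines was TGFA, a ligand of the EGF receptor. It went from 17.7 ± 5.19 CPM (SD, n = 2 control lines) to 134 ± 59.8 CPM (SD, n = 3 KO lines), a log2 fold change of 2.86 ± 0.09 (SE). SERPINB2, an inhibitor of plasminogen activators, rose by 2.68 ± 0.33, and PLAT, the tissue plasminogen activator, by 1.42 ± 0.08. SLITRK6, a neuronal transmembrane protein, rose by 2.26 ± 0.14, and FLNC, an actin-binding filamin, by 2.04 ± 0.20. The rising set was completed by FAM84B, TSPAN9, FAM78A, MYPN and HOXA5, at 1.23 to 1.64. FLNC differed by −1.37 between NT and Par, and TGFA by 0.60.

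Among the falling genes of SKmel147, CD33, a sialic acid-binding receptor, changed by −4.09 ± 0.14, and SV2A, a synaptic vesicle protein, by −2.62 ± 0.10. PTPRD, a receptor tyrosine phosphatase, had 0 counts in both KO1.4 libraries, which was at least 345-fold lower than in the controls at 20.6 CPM (floor of 3 counts over both libraries). Its log2 fold change was −3.83 in KO1.5 and −2.02 in KO3.20. No DNA was measured, so loss of the gene itself in KO1.4 cannot be told apart from loss of its RNA. Genes of metabolism were MGST1, a microsomal glutathione transferase, at −1.80 ± 0.12, UCP2, a mitochondrial carrier, at −1.38 ± 0.10, and RRAGD, a GTPase of amino acid sensing, at −1.47 ± 0.11. PAPPA2, RPS6KA2, MCOLN3 and PLXNA2 completed the set at −1.29 to −1.71. The adjusted p of these 20 genes ranged from 1.86e-08 to 0.000246 (edgeR quasi-likelihood test, BH). With the line as the replicate, SV2A and PAPPA2 still passed, both at an adjusted p of 0.0394 (edgeR, BH), and the other 18 did not.

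In all, 3245 of 18361 tested genes were called in SKmel147, 1482 higher and 1763 lower in the KO lines, and 741 of them differed by more than 2-fold. NT differed from Par in 1702 genes, a count that went from 436 without NT R1 to 2989 after the GC and length correction. That difference followed GC content across genes at rho of −0.526, KO against controls at −0.158, and the libraries of 1 line differed with GC content at 0.495 to 0.779 in size, with both signs. Changed in every KO line were 622 genes, 291 higher and 331 lower. Simulations without a KO effect, whose lines drifted as the control lines did, gave a median of 3412 calls and of 348.5 in every KO line, with a highest value of 374 for the latter. Taking the line as the replicate, 13 genes passed, 1 higher and 12 lower, while voom with the line as a block called 572. An unadjusted p under 0.05 was reached by 2501 of 19729 genes with the line as the replicate (edgeR), where 986 would be expected by chance. Against NT alone the count was 2076, of which 1623 were among the 3245, without KO3.20 it was 2094, and leaving out any KO library lowered the count for every KO line to between 233 and 378. After the GC and length correction 5348 genes were called, 2572 higher and 2776 lower, and 1452 in every KO line, and against Par alone 1032 changed in every KO line.

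The fold changes of the SKmel147 KO lines correlated across genes at r of 0.638 for KO1.4 and KO1.5, 0.657 for KO1.4 and KO3.20, and 0.571 for KO1.5 and KO3.20. Unchanged lines simulated against the same controls gave 0.336. The covariances were 0.183 to 0.206 against a simulated 0.0250, and with the controls split between the lines r was 0.242 to 0.308. The unchanged lines, here and for 501mel below, held no drift between lines. Drift of the shared controls enters the fold changes of every KO line. No r or covariance is given for drifting lines, so these values do not separate a KO effect from drift. KO1.4 and KO1.5 shared 375 rising and 459 falling calls, where independent lists would share 39.5 and 50.9, unchanged lines against the same controls 0 and 0, and lines that drift like the control lines 400 and 378 (medians of 10 simulations). KO1.4 and KO3.20 shared 516 and 501, against 399.5 and 377.5 for drifting lines. For KO1.5 and KO3.20 the numbers were 412 and 492, against 426 and 388. In 501mel, KO1.8 and KO5.2 correlated at 0.549 against a simulated 0.336, with a covariance of 0.249 against 0.0109 and r of 0.416 and 0.373 with split controls. They shared 1995 rising and 1898 falling calls, against 866 and 880 for independent lists, 0 and 0 for unchanged lines and 681.5 and 699.5 for drifting lines. Genes are not independent replicates in these correlations.

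**Figure D2:**
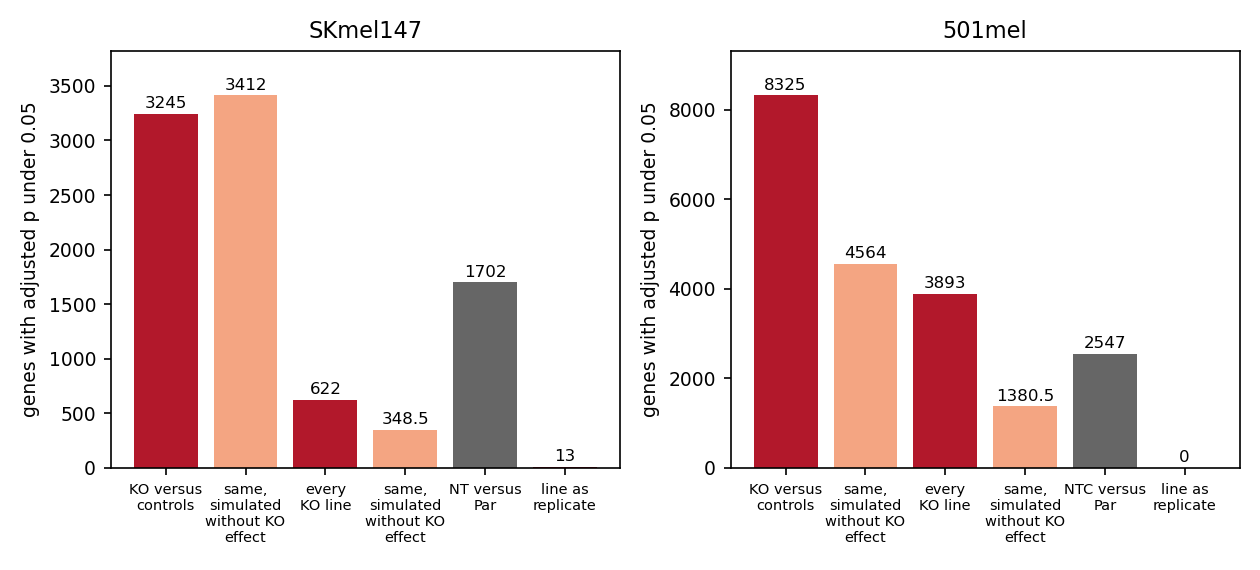
Number of genes with an adjusted p under 0.05 (y axis) in each cell line: KO against controls, changed in every KO line, the same counts in simulations without a KO effect (pale bars, medians of 10), the transduced control against Par (grey), and KO against controls with the line as the replicate. In SKmel147 3245 genes were called against 3412 in the simulations, and in 501mel 8325 against 4564.

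Of the p53 target genes in SKmel147, 14 of 26 rose and 1 fell, and 17 rose and 1 fell with p-values adjusted over the list alone. FUCA1, a lysosomal fucosidase, rose by 1.69 ± 0.15, and TP53INP1, a stress-induced nuclear protein, by 0.94 ± 0.11, while SESN2 fell by 0.39 on the log2 scale. CDKN1A, a cell cycle inhibitor, rose by 0.55 ± 0.08, and MDM2, the ubiquitin ligase of p53, by 0.45 ± 0.12; both were named after their values had been seen, and both passed in KO1.5 but not in KO1.4 or KO3.20 (CDKN1A at 1.06, 0.31 and 0.28). The median of the list was 0.46, with 0.29 in KO1.4, 0.65 in KO1.5 and 0.33 in KO3.20, against 0.04 between NT and Par. The list passed camera (adjusted p = 1.34e-08; 3.88e-08 with the line as the replicate) and did not pass with an estimated correlation (adjusted p = 0.214).

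Genes of cholesterol synthesis and uptake fell in SKmel147: 15 of 23 fell and 1 rose, and 18 fell and 1 rose when adjusted over the list alone. FDFT1, squalene synthase, changed by −0.61 ± 0.08, while TM7SF2, a sterol reductase, rose by 0.74 ± 0.15, with −0.23 in KO1.5. Genes of the integrated stress response and amino acid synthesis also fell, 13 of 23 with 1 rising, and by the same numbers when adjusted over the list alone. SHMT2 and PSAT1, enzymes of glycine and serine synthesis, changed by −1.08 ± 0.09 and −0.94 ± 0.07, and SLC7A11, the cystine transporter, rose by 0.64 ± 0.09. The medians were −0.39 for cholesterol and −0.53 for the stress response list (camera, adjusted p = 1.56e-07 and 4.68e-06; 0.214 for both with an estimated correlation). Between NT and Par the cholesterol list also fell, with a median of −0.34 (camera, adjusted p = 0.000158), and 4 of its members fell against NT alone and 7 without KO3.20; the stress response list was at 0.13 there (adjusted p = 0.0963).

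Antigen presentation, G2/M and endothelial lists also passed in SKmel147. HLA-DMB and HLA-DPA1, of the class II pathway, were among 11 of 25 antigen presentation genes that rose, while CTSS, a lysosomal protease, changed by −3.01 ± 0.14 and CD274, the ligand PD-L1, by −0.88 ± 0.14, among 5 that fell; adjusted over the list alone, 13 rose and 5 fell. The list median was 0.42 (camera, adjusted p = 0.00765; 0.819 with an estimated correlation), but it was −0.76 between NT and Par, against Par alone its direction reversed, and without KO1.4 it did not pass (camera, adjusted p = 0.0603). Against Par alone 6 members rose, and the number that fell was 2 against NT alone or without KO1.5, 3 without KO3.20 and as low as 3 without a single library. Of 30 G2/M genes 4 fell, also when adjusted over the list alone, among them CENPF at −0.55 ± 0.07 and CDC20 at −0.41 ± 0.07. The G2/M median was −0.11 (camera, adjusted p = 0.0424; 0.819 with an estimated correlation), and the direction reversed against Par alone, NT lying above Par at 0.24. After the GC and length correction 9 G2/M genes fell, and 2 did against Par alone or without KO1.5. This call was lost when Par R1, NT R1, KO1.4 R1, KO1.5 R2 or KO3.20 R1 was left out, with adjusted p of 0.101, 0.379, 0.128, 0.0869 and 0.0833 (camera), and without the line KO1.5 at 0.222. Of 4 endothelial markers tested, TIE1 and ROBO4 fell, ROBO4 at −1.36 ± 0.14 (camera, adjusted p = 0.0121; 0.214 with an estimated correlation; 0.162 against NT alone, 0.208 without a low-count filter and 0.171 with the line as the replicate), the same 2 when adjusted over the list alone.

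The other 23 lists did not pass in SKmel147, with adjusted p of 0.0668 to 0.977 (camera), though against NT alone 14 of the 29 passed. Members moved both ways among collagens and matrix genes, where 11 of 28 rose and 6 fell (13 and 6 adjusted over the list alone), such as COL1A1 at 1.67 ± 0.21, FN1 at 0.70 ± 0.06 and FBN2 at −1.20 ± 0.07. Of 27 markers of undifferentiated and invasive melanoma 7 rose and 6 fell (8 and 6 adjusted over the list alone), with WNT5A at 1.15 ± 0.11, SNAI2 at 0.70 ± 0.09 and LOX at −1.03 ± 0.11. The control lines lay far apart for FN1, at 128.4 ± 76.1 CPM (SD between lines), against 200.5 ± 87.3 CPM in the KO lines. SNAI2 was at 45.9 ± 19.0 CPM in the control lines and 73.0 ± 21.75 CPM in the KO lines. Relative to its mean, the control SD was smaller for COL1A1 (2.235 ± 0.47 CPM), FBN2 (138.3 ± 8.16), WNT5A (40 ± 11.7) and LOX (24.1 ± 6.73). Among PBAF subunits PHF10 rose by 0.36 ± 0.09, and SMARCA2, a catalytic subunit of SWI/SNF complexes, fell in both cell lines, at −0.51 ± 0.07 in SKmel147 and −0.71 ± 0.08 in 501mel. Among the list members named for SKmel147, SESN2, SLC7A11, HLA-DMB, FN1, SNAI2 and PHF10 did not pass in every KO line. Between NT and Par, where no KO was involved, 15 of 29 lists passed, 12 of them downward.

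In 501mel, TNS1, an adhesion adaptor, rose by 4.36 ± 0.12 (SE), GPC5, a glypican, by 3.19 ± 0.10, and EMP1, a membrane protein, by 2.86 ± 0.05. VGF, a secreted neuropeptide precursor, rose from 67.6 ± 36.3 CPM (SD, n = 2 control lines) to 320 ± 84.3 CPM (SD, n = 2 KO lines), a log2 fold change of 2.33 ± 0.04. ERBB3, a receptor kinase of the melanocyte lineage, rose by 2.14 ± 0.07, and ADD2, STMN3, LCP1, LINGO1 and PAEP rose by 1.73 to 2.61. NTC lay on the other side of Par for several of them, with differences of −3.91 for TNS1, −2.90 for GPC5 and −2.81 for EMP1. PAEP and LPL lie on chromosomes 9 and 8, whose genes were shifted as a whole in KO5.2, but against the direction of their own changes.

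Among the falling genes of 501mel, ACTL8, an actin-like gene of the germline, changed by −6.00 ± 0.07, KCNG1, a potassium channel subunit, by −5.93 ± 0.18 and NLRP1, an inflammasome sensor, by −6.42 ± 0.25. EMILIN1, a matrix glycoprotein, changed by −4.24 ± 0.11 and LPL, lipoprotein lipase, by −4.84 ± 0.16. The cytidine deaminase genes APOBEC3B and APOBEC3A changed by −2.89 ± 0.07 and −2.94 ± 0.10; they are near-identical in part, so reads could be shared between them. IGSF10, TACC2 and KCNE4 were at −4.71, −4.19 and −2.22. NTC was higher than Par for all 10, by 0.57 to 1.78. The adjusted p of the 20 genes ranged from 2.00e-16 to 1.53e-09 (edgeR quasi-likelihood test, BH), and none passed with the line as the replicate.

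In all, 8325 of 16230 tested genes were called in 501mel, 4016 higher and 4309 lower, and 1182 of them by more than 2-fold. NTC differed from Par in 2547 genes, but in 1310 without NTC R2 and 1590 by the DESeq2 Wald test. Changed in both KO lines were 3893 genes, 1995 higher and 1898 lower. The simulations without a KO effect gave a median of 4564 calls, and of 1380.5 in both KO lines with a highest value of 1429. When lines were the replicates, 0 genes passed (edgeR), although 2360 had an unadjusted p under 0.05, where 856 would be expected by chance. The voom fit with the line as a block called 947.

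TGF-beta response genes fell in 501mel, 16 of 24 with 2 rising, and by the same numbers when adjusted over the list alone. LTBP1, which binds latent TGF-beta, changed by −2.71 ± 0.09 and BAMBI, a decoy receptor that dampens the pathway, by −0.78 ± 0.04, while ID3 and ID4, inhibitors of DNA binding, rose by 0.83 ± 0.10 and 0.31 ± 0.11, with 0.16 and 0.13 in KO1.8, where neither passed. The median was −0.30 (camera, adjusted p = 0.00248; 0.212 with an estimated correlation), against 0.11 between NTC and Par. Without KO5.2 the list still passed, with 9 of 23 falling. Integrated stress response genes fell, 16 of 24 with 1 rising (17 and 1 adjusted over the list alone), with DDIT3, a stress-induced transcription factor, at −1.34 ± 0.09, VLDLR at −0.90 ± 0.05 and HSP90B1, a chaperone, rising by 0.20 ± 0.04 but at −0.11 in KO1.8. Its median was −0.36 (camera, adjusted p = 0.000246; 0.619 with an estimated correlation), but NTC also lay below Par at −0.30, and against NTC alone the list did not pass (adjusted p = 0.139).

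AP-1 factors and YAP/TEAD targets fell in 501mel. Of 15 AP-1 genes 11 fell and 2 rose (12 and 2 adjusted over the list alone), with BATF at −4.28 ± 0.37, FOSL2 rising by 0.85 ± 0.07, and MAFF rising by 0.13 ± 0.05 but at −0.0184 against Par alone and −0.11 in KO1.8. Of 18 YAP/TEAD genes 12 fell and 4 rose, also when adjusted over the list alone, with CYR61, a secreted matrix protein, at −1.33 ± 0.09, TEAD1 at −0.54 ± 0.04, and LATS2, a kinase that restrains YAP, rising by 0.36 ± 0.05. The medians were −0.58 and −0.31 (camera, adjusted p = 0.0491 and 0.0476; 0.321 for both with an estimated correlation). Between NTC and Par they were at −0.14 and 0.35 (camera, adjusted p = 0.0115 and 4.23e-08). Without KO5.2 6 AP-1 genes fell, and against Par alone 7 YAP/TEAD genes. Neither list passed without KO1.8 (adjusted p = 0.0585 and 0.203) or without KO5.2 (0.244 and 0.0664), AP-1 did not pass against NTC alone (0.310), and YAP/TEAD did not pass against Par alone (0.708), all by camera. AP-1 also did not pass without Par R1, Par R2 or KO1.8 R2 (adjusted p = 0.0970, 0.0537 and 0.0535), nor YAP/TEAD without KO1.8 R1 or KO1.8 R2 (0.0522 and 0.0535), by camera. With the replicate block the adjusted p was 0.0747 for AP-1 and 0.0587 for YAP/TEAD, and with the line as the replicate 0.297 for YAP/TEAD (camera).

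Melanocyte differentiation genes moved both ways in 501mel, with 14 of 30 rising and 8 falling, also when adjusted over the list alone. EDNRB, the endothelin receptor of melanoblasts, rose by 1.02 ± 0.04 beside ERBB3, whereas TYRP1, an enzyme of pigment synthesis, changed by −0.99 ± 0.04 and S100B by −0.62 ± 0.06. TYRP1 was at −0.07 in KO1.8, which did not pass, and at −1.92 in KO5.2. G2/M genes rose, 14 of 30 with 0 falling, also when adjusted over the list alone, such as BUB1B at 0.49 ± 0.04 and NUSAP1 at 0.46 ± 0.04. Both lists had a median of 0.10 (camera, adjusted p = 0.0165 for both; 0.597 and 0.346 with an estimated correlation). NTC lay below Par in the melanocyte list at −0.20, and it did not pass against Par alone (camera, adjusted p = 0.369) or with the line as the replicate (0.0645); 9 of its genes rose against Par alone, and 5 fell without KO5.2. Without KO5.2 neither list passed (camera, adjusted p = 0.0664 for melanocyte and 0.244 for G2/M genes).

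Matrix proteases and cancer-testis genes also passed in 501mel. CTSB, a lysosomal protease, rose by 1.28 ± 0.04 and PLAT by 0.74 ± 0.05, among 7 of 16 that rose, while 3 fell, among them ADAMTS1 at −1.09 ± 0.08; these numbers held when adjusted over the list alone. CTSL, at −0.14 ± 0.04, was at 0.10 against Par alone. The protease median was 0.27 (camera, adjusted p = 0.0190; 0.321 with an estimated correlation; 0.0893 against NTC alone, 0.137 without a low-count filter and 0.370 with the line as the replicate). Of 13 cancer-testis genes 6 fell and 4 rose, also when adjusted over the list alone, with MAGEA4 at −3.78 ± 0.07, MAGEA1 at −1.28 ± 0.05 and SSX2 at 0.49 ± 0.04; against NTC alone 2 rose. The KO lines differed for MAGEA4, at −0.29 in KO1.8 and −7.26 in KO5.2. Its median was −0.01 and its mean −0.69 (camera, adjusted p = 3.77e-05; 0.207 with an estimated correlation; 0.117 without a low-count filter and 0.690 with the line as the replicate), and the median and the mean differed in size because a few members changed far more than the rest. The other 19 lists of 501mel did not pass (camera, adjusted p of 0.0724 to 0.990), and 5 lists passed between NTC and Par. With the line as the replicate no member of a list that passed was called by itself in either cell line. Without KO5.2, 2 of the 8 lists still passed, TGF-beta and the integrated stress response.

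**Figure D3:**
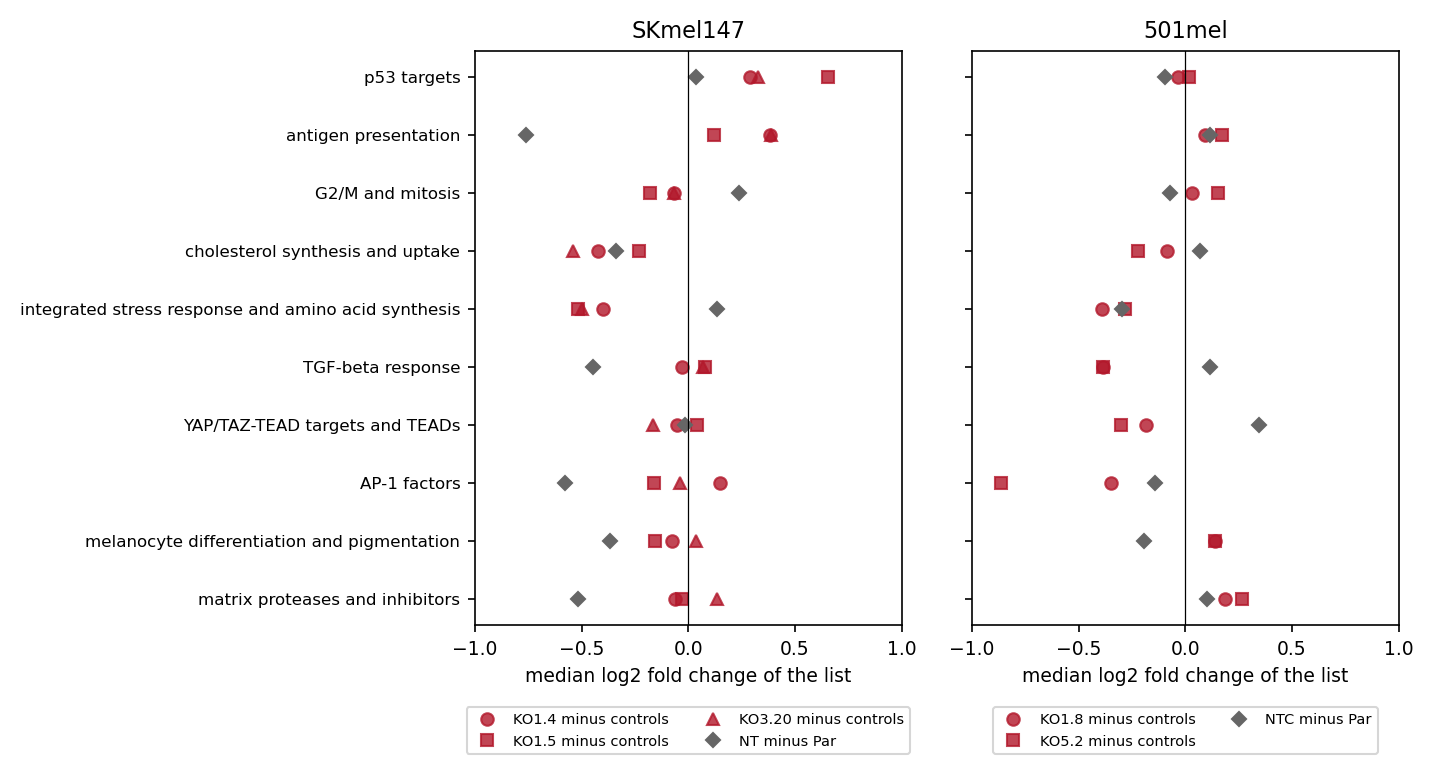
Median log2 fold change (x axis) of 10 gene lists in each KO line against the mean of the controls (red) and in the transduced control against Par (grey). For p53 targets in SKmel147 the KO lines sat at 0.29, 0.65 and 0.33 and NT against Par at 0.04, whereas for antigen presentation NT against Par sat at −0.76.

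The KO effect differed between the cell lines for 4156 of 19518 genes, 2206 higher and 1950 lower in SKmel147. MCAM, a melanoma adhesion molecule, rose by 2.37 ± 0.06 in 501mel and was at 0.11 ± 0.09 in SKmel147, and EMP1 rose by 2.86 ± 0.05 and was at 0.00 ± 0.07. RPS6KA2, a ribosomal S6 kinase, fell by 1.71 on the log2 scale in SKmel147 and rose by 0.57 ± 0.05 in 501mel, at 0.10 in KO1.8 and 1.05 in KO5.2. MAGEA4 rose by 0.35 ± 0.09 in SKmel147, where no KO line passed by itself, and was at −0.29 and −7.26 in the 501mel KO lines, and JAM3, a junctional adhesion molecule, was at 0.20 ± 0.07 there and at −2.77 ± 0.08 in 501mel. The adjusted p of the difference for the 10 genes so named was at most 4.49e-09 (edgeR quasi-likelihood test, BH), but none of the 10 passed with the line as the replicate. Lines as replicates gave 3 genes, and voom with the line as a block called 421. In 566 of the 4156 genes the calls in the cell lines had opposite directions, and 45 of these held in every KO line of both.

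Between the cell lines 9 lists differed in their KO effect by camera, none of them with an estimated correlation (lowest adjusted p = 0.0946). Target genes of p53 were higher in SKmel147, with a median of 0.46 against 0.01 in 501mel, where 9 of 22 rose and 7 fell (the same when adjusted over the list alone; 4 rose against Par alone), MDM2 among the latter at −0.62 ± 0.05. Collagens and matrix genes had medians of 0.29 in SKmel147 and −0.59 in 501mel, with LAMB1 in 501mel at −1.17 ± 0.04. G2/M genes were at −0.11 and 0.10, and DNA replication genes at −0.10 and 0.10, with RRM2 in 501mel at 0.66 ± 0.04. Interferon-stimulated genes were at 0.16 and −0.12, with SAMD9 in 501mel at −1.79 ± 0.08. Cholesterol genes were at −0.39 and −0.19, and in 501mel 14 of 23 fell and 3 rose (7 fell against Par alone), with INSIG1 at −0.51 ± 0.05. TGF-beta, YAP/TEAD and cancer-testis genes completed the 9 lists. In several lists NT and Par of SKmel147 differed by more in size than the KO median of SKmel147. These differences were −0.31 for collagens, −0.54 for interferon-stimulated, −0.45 for TGF-beta, 0.24 for G2/M and 0.26 for DNA replication genes. For collagens the median difference between the cell lines was larger than that, at 0.87. The G2/M direction in SKmel147 reversed against Par alone.

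Genes that changed in the same direction in both cell lines included PLEKHG1, which rose by 0.99 ± 0.10 in SKmel147 and 1.92 ± 0.08 in 501mel, and RNF182, at 0.95 ± 0.11 and 1.47 ± 0.09. UBL3, SLC26A2 and SDC3 rose in both by at least 0.84. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was at −1.18 ± 0.18 and −1.08 ± 0.11, AACS, acetoacetyl-CoA synthetase, at −0.95 ± 0.11 and −0.95 ± 0.07, and UCP2 at −1.38 ± 0.10 and −1.01 ± 0.12. RAP1GAP2, a GTPase activator, was at −1.82 ± 0.15 and −1.13 ± 0.06, and FSTL1 in 501mel at −1.74 ± 0.05. The size of the change differed by the interaction test for PLEKHG1 (adjusted p = 8.42e-05), RNF182 (0.0348), SLC26A2 (0.0277), SDC3 (0.0293), RAP1GAP2 (0.00554) and FSTL1 (0.000180), and no difference passed for the other 4 (edgeR quasi-likelihood test, BH). The naming rule was met with the same direction in both cell lines by 63 genes, 24 rising and 39 falling, and with opposite directions by 23. Their adjusted p was at most 0.000818 in SKmel147 and 5.48e-06 in 501mel for the 10 named (edgeR quasi-likelihood test, BH).

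Among 14681 genes tested in both, 473 rose in both against 307 expected from independent lists, and 601 fell in both against 355, while 285 and 281 went in opposite directions against 321 and 340. The ratio of shared to expected calls was 1.62, and 7.63 among calls of more than 2-fold, where opposite calls also exceeded expectation, 13 against 6.39 and 16 against 2.96. For the transduced controls against Par, 43 genes rose in both against 39.0 expected, and 89 fell in both against 68.9. Opposite calls there were 95 and 97, against 51.1 and 52.7. The fold changes of KO against controls correlated across genes at r of 0.117 and rho of 0.125. For the transduced controls against Par r was −0.0766 and rho −0.0834. Genes are not independent replicates here, so no p-value is attached.

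Whole chromosomes, by the rule given below, were shifted in single lines. In KO5.2 of 501mel the median log2 fold change was −0.51 over 562 genes of chromosome 9, −0.42 over 440 genes of chromosome 14 and 0.31 over 476 genes of chromosome 8, while KO1.8 was at −0.03, −0.04 and 0.00. In KO3.20 of SKmel147 it was −0.28 over 391 genes of chromosome 20 and 0.37 over 162 genes of chromosome 21. The other SKmel147 KO lines lay between 0.03 and 0.05 on chromosome 20 and between 0.02 and 0.09 on chromosome 21. NT against Par was at 0.39 over 328 genes of chromosome 13 and at −0.53 over 348 genes of chromosome 22, and after the GC and length correction at 0.31 and −0.33. These were the chromosomes on which at least 90% of windows of 100 neighbouring genes had a median of at least 0.2 in size. Shifts short of that rule were shared by both KO lines of 501mel. Chromosome 15 was at 0.21 in KO1.8 and 0.23 in KO5.2, chromosome 20 at 0.25 and 0.23, and chromosome 19 at 0.20 and 0.14. The simulations without a KO effect let each gene drift by itself and hold no such regional shifts. The 3 chromosomes of KO5.2 held 1079 of its 8684 calls. In KO1.4 of SKmel147 chromosome 9 was at −0.28, with 458 of its 642 genes in windows shifted down, which fell short of the rule.

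**Figure D4:**
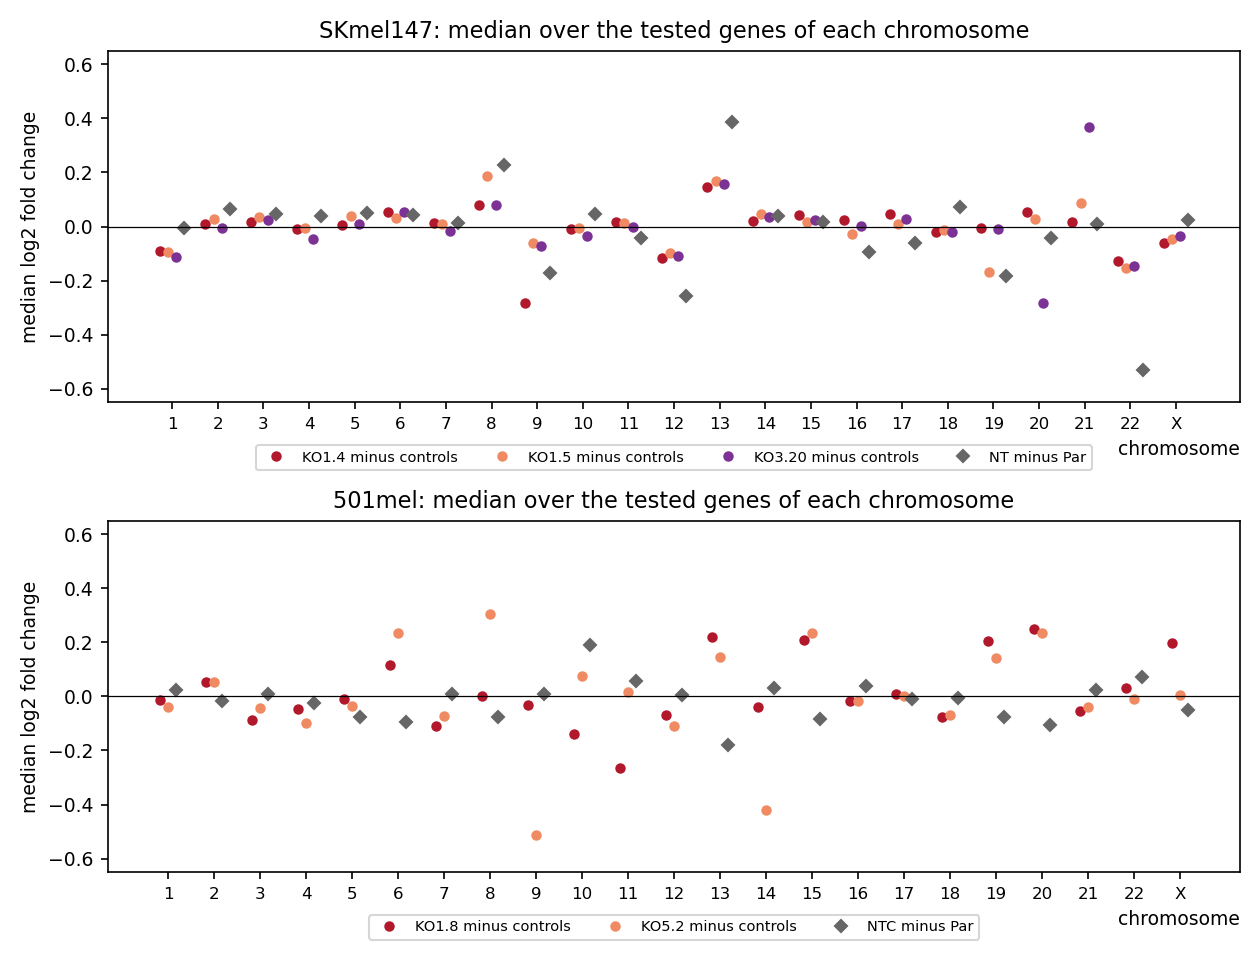
Median log2 fold change (y axis) of the tested genes of each chromosome (x axis) in each KO line against the mean of the controls and in the transduced control against Par. Chromosomes 9 and 14 stand out in KO5.2 at −0.51 and −0.42, and chromosome 22 in NT against Par at −0.53.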

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

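Of the tests of the p53 targets in this part, those of transduction and of GC content were chosen only after the result was seen, and their splits of the lines were planned before. The KO effect differed between SKmel147 and 501mel for 4156 genes by the interaction test (edgeR quasi-likelihood test, BH), and this difference is what drew attention to each result here. With the line as the replicate 3 genes differed. Of 60 random splits of the libraries 1 gave as many genes (1505 real, 19 the highest other). Of the 60 splits of whole lines, chosen after the result was seen, 3 did so, the real one included. The highest, at 2548, kept the real KO grouping of both cell lines and turned its direction in 501mel. The other, at 1769, kept the real grouping of 501mel. Both hold the real KO effect of at least 1 cell line, so these splits cannot decide, and chance was not excluded. Positive values mean a higher KO effect in SKmel147.

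MAGEA4, a cancer-testis antigen, differed by 4.13 ± 0.14 (SE), with −0.29 in KO1.8 and −7.26 in KO5.2 of 501mel, and TACC2, a centrosomal protein, by 4.24 ± 0.16. The adhesion molecule JAM3 differed by 2.98 ± 0.11 and PSD3 by 2.66 ± 0.11. APOBEC3B differed by 2.595 ± 0.10, with reads that near-identical family members can share. The membrane protein EMP1 differed by −2.85 ± 0.09, ADD2, which links spectrin to actin, by −2.42 ± 0.09, and the adhesion molecule MCAM by −2.25 ± 0.12. RPS6KA2 differed by −2.27 ± 0.13 and EMC10 by −3.62 ± 0.21.

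By camera, G2/M genes differed with an adjusted p of 2.86e-05 and DNA replication genes with 0.000573, both lower in SKmel147. Target genes of p53 differed with an adjusted p of 0.000393 and interferon-stimulated genes with 0.000854, both higher in SKmel147. YAP/TEAD targets and cancer-testis genes each differed with an adjusted p of 0.00112, and collagens and TGF-beta response genes each with 0.00186, all higher in SKmel147 (camera). Cholesterol genes differed with an adjusted p of 0.00561 and were lower in SKmel147 (camera). None of the 9 lists passed with an estimated correlation, where the lowest adjusted p was 0.0946.

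For the rise of p53 targets in SKmel147, the median of the list against NT alone was 0.48 ± 0.08 (SE, n = 26 genes). This argues against transduction and Cas9 expression as the whole cause only as far as 1 NT line can. The SE came from resampling the genes as if they were independent, and it holds no spread between lines or libraries. The first test chosen, NT against Par, gave 0.04 and decided nothing. The labels do not say whether the guide in NT cuts, so DNA cutting as such was not tested. Trends on GC content and length were argued against, since after their correction the list passed with an adjusted p of 6.53e-10 (camera). Differences between lines unrelated to the KO stay open, although the list passed with the line as the replicate (camera, adjusted p = 3.88e-08) and in each KO line: this rests on a preset correlation between genes, and with an estimated one the adjusted p was 0.214. The 10 splits of the 5 lines are too few for a share under 0.05; 3 gave a list p as small, the real one at 4.61e-10 and the best of the others at 4.49e-14 (camera), and both others set the controls and 1 KO line against the other KO lines.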

How the results depend on the processing

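The correction for GC content and length was chosen only after the data had been seen; the other alternatives were planned. Both DESeq2 size factors and the replicate block kept the numbers of genes and lists within 1.5 times and ARID2 past the threshold. The DESeq2 Wald test, run for the numbers of genes and ARID2 but not for lists, did so except for NTC against Par at 1590 genes. None of these was run for the overlap between the cell lines. The labels do not say whether the replicate numbers pair libraries. Deviations of libraries with the same number correlated at −0.72 to 0.77 over 10 pairs of lines in SKmel147 and at 0.0472 to 0.356 over 6 in 501mel. With a replicate block SKmel147 gave 3083 calls, 571 in every KO line and 6 lists, 501mel 9045, 4404 and 6, and the difference between the cell lines 4022. Under that block AP-1 and YAP/TEAD in 501mel did not pass (camera, adjusted p = 0.0747 and 0.0587). With the line as the replicate the counts were 13 in SKmel147, 0 in 501mel (edgeR; 2360 at an unadjusted p under 0.05; voom 947) and 3 for the difference, ARID2 was at −0.42 and −0.69 and did not pass, and 9 lists passed in SKmel147, among them 5 of the 6, and 5 in 501mel. The voom fit gave 572, 947 and 421, with ARID2 in SKmel147 at −0.43 and not past the threshold. A 2-fold limit left 741 and 1182 calls. Against the transduced control alone SKmel147 gave 2076 calls and 14 lists and 501mel 5 lists, and ITGA5 at 0.012, PHLDA1 at 0.14 and ID3 at 0.18 in SKmel147 turned direction. Against Par alone 1032 genes changed in every SKmel147 KO line, the lists antigen presentation (camera, adjusted p = 0.577) and G2/M (camera, adjusted p = 0.949) turned direction in SKmel147, and so did MAFF at −0.0184, CTSL at 0.10 and PERP at −0.015 in 501mel. Without a low-count filter NT against Par gave 2680. Without KO3.20 SKmel147 gave 2094 calls, and without KO5.2 501mel gave 2 lists. With an estimated correlation 0 lists passed in either cell line (camera), and 6 and 8 did with the preset one. After the GC correction SKmel147 gave 5348 calls, among them 3234 of the 3245, 1452 in every KO line and 2989 for NT against Par; its biological coefficient of variation went from 0.134 to 0.0978. Leaving out 1 library at a time, with the lone library assumed to vary like the others, SKmel147 ranged from 2232 to 3349 calls, 233 to 721 in every KO line, 436 to 2375 for NT against Par, −0.47 to −0.39 for ARID2 and 5 to 8 lists. The ranges in 501mel were 7330 to 7897, 3132 to 3767, 1310 to 2652, −0.76 to −0.71 and 6 to 9, and for the difference 3245 to 4723. NT against Par fell to 436 without NT R1, 889 without Par R2, 1127 without KO1.4 R1 and 1096 without KO1.4 R2, and NTC against Par to 1328 and 1310 without NTC R1 and R2. The count for every SKmel147 KO line was 233 and 244 without KO1.4 R1 and R2, 293 and 378 without KO1.5 R1 and R2, and 309 and 296 without KO3.20 R1 and R2. For all of these, the cause was not tested. The lowest total was 16749707 counts, and the effect of depth was not tested.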

Other observations

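Of the tests in this part, the simulations without a KO effect, the splits of whole lines for the gene counts, the GC correction of the gene counts and the test for gain or loss of chromosome copies were chosen only after the results were seen. The splits of the libraries and the regional copy number test were planned. The GC test of whole chromosomes was written before its own result. It rests on the GC and length correction, which was chosen after the data had been seen.

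Several gene groups moved both ways within a cell line. Among inflammatory genes of SKmel147, the cytokine genes CXCL5 and IL1A rose by 1.04 ± 0.11 (SE) and 1.04 ± 0.12, and IL1B fell by 1.39 on the log2 scale, though NT lay below Par by more, at 44.0 against 274 CPM; 5 of 26 members rose and 2 fell (6 and 2 adjusted over the list alone). Among genes downstream of MAPK signalling, EGR1, an immediate early transcription factor, rose by 1.89 ± 0.14 in SKmel147 and fell by 1.85 on the log2 scale in 501mel, where the phosphatase gene DUSP4 rose by 1.19 ± 0.04 and CCND1, cyclin D1, by 0.64 ± 0.03. The glucose transporter gene SLC2A1 rose in both, by 0.41 ± 0.08 and 1.26 ± 0.05. Single KO lines that did not pass were KO3.20 for IL1A, at 0.34, KO1.5 for SLC2A1, at 0.09, and KO1.8 for EGR1, at −0.46. None of the lists these genes belong to passed camera in either cell line.

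ERBB3 rose in both cell lines, by 2.01 ± 0.21 in SKmel147 and 2.14 ± 0.07 in 501mel, but KO1.5 of SKmel147, at 0.72, did not pass. CTSS, a lysosomal protease, fell in both, at −3.01 ± 0.14 and −3.95 ± 0.30. Among subunits of SWI/SNF complexes in 501mel, PBRM1 and BRD7, which belong to PBAF, were at −0.24 ± 0.05 and 0.25 ± 0.04, and the shared subunits BCL7A and SMARCD2 at 0.28 ± 0.05 and −0.24 ± 0.04. Markers of keratinocytes, fibroblasts and immune cells did not pass as lists in SKmel147 (camera, adjusted p = 0.737, 0.230 and 0.691), nor did the first pair in 501mel (0.953 and 0.108). With the line as the replicate the fibroblast list passed upward in SKmel147 and downward in 501mel (camera, adjusted p = 0.0367 and 0.0407). Of its members 2 of 6 rose and 1 fell in SKmel147, and 4 of 5 fell and 0 rose in 501mel.

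The number of called genes was weighed against differences between lines. In fits with 1 coefficient per group, 1 of 100 splits called as many genes in SKmel147 (1255 real, 202 the highest other) and 1 of 35 in 501mel (3286 and 0), but splits that divided lines called at most 4 and 0 genes, and the 10 and 3 splits of whole lines are too few for a share under 0.05. GC content and length were argued against as the main cause. After the correction 99.7% of the calls in SKmel147 and 96.6% in 501mel stayed with the same sign. In SKmel147 15.8% of the calls of single KO lines lay among neighbours shifted the same way. Windows shifted either way held 7.73 to 10.6% of all genes, whatever the sign of the gene, so these shares are unlike measures. The 15.8% argued against regional copy number of the KO lines as the main cause. Shifts of 1 control line are weakened in the control mean and can miss the limit of 0.2, so they were not covered. Between NT and Par the shares were 39.2% and 24.2%. Chromosome 13, at 0.39 there, was at 0.14, 0.17 and 0.16 in the KO lines. Differences between lines unrelated to the KO may account for the number of calls. The simulations cannot decide this, since their drift was taken from 1 pair of control lines. In SKmel147 they gave 3412 calls against 3245, though at most 374 in every KO line against 622. With GC trends removed they gave 4387 against 5348, and at most 594 against 1452. In 501mel, without that removal, the simulations gave 4564 against 8325, and at most 1429 against 3893. With GC trends removed, the simulations of 501mel gave 4827 calls and at most 1586 in both KO lines. The KO lines did not spread like the control lines. At a mean log2 CPM of at least 3, the median SD in SKmel147 was 0.112 between KO lines and 0.155 between control lines. In 501mel it was 0.144 and 0.0839. The simulated counts may thus be too high in SKmel147 and too low in 501mel. Regional copy number stays open in 501mel at 30.9%. There, windows shifted either way held 25.2% and 29.4% of all genes, whatever the sign of the gene. For the number of lists passed chance was not excluded, with 55 of 100 splits as high in SKmel147 (5 real, 15 the highest other) and 12 of 35 in 501mel (4 and 6).

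The shifts of whole chromosomes in KO3.20 and KO5.2 were weighed too. Trends on GC content and length were argued against, since at least 97.0% of each median was left after the correction in SKmel147 and 95.4% in 501mel. Gain or loss of chromosome copies was left undecided: at least 79.8% of the tested genes of such a chromosome had the sign of its median in SKmel147 and 75.8% in 501mel, but the chromosomes had been picked by medians of neighbouring genes, which fixes a large share. No DNA was measured, and no biological explanation was tested.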
